A study of Homo sapiens with 2 samples.

How the data were processed

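Gene expression was measured in HT1080, an established human fibrosarcoma cell line, on 2 Affymetrix Human Gene 2.0 ST arrays. This whole-transcript array reads each gene through a set of short probes that are summarised to 1 value per probe set. Per the labels' protocols, cells were infected with virus carrying a short hairpin RNA (shRNA) and harvested 48 hours later. One array holds RNA of cells given an shRNA against cMyc, the other RNA of cells given a non-targeting shRNA, and the labels name 1 sample of each. RNA was extracted with TRIZOL, checked for integrity, purified on columns with DNase treatment and turned into biotin-labelled cDNA, per the labels' protocols.

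The table deposited by the authors holds log2 expression values for 53617 probe sets, between 1.41 and 13.9. The log base was inferred from this range and is not stated, so folds assume base 2; the values are levels, not centred or signed. Affymetrix Expression Console made the values, per the submitters' processing notes, and its version and the methods of background correction, normalization and summarization are not given in the sources used here. The medians of the 2 columns are 3.68 and 3.73, and their sorted values differ by at most 0.12, so the columns were on nearly the same scale as deposited. The table has no detection calls and no scanner intensities, so the precision of a single value is unknown and is limited by having 2 arrays.

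Gene names came from GEO's platform annotation. It gave 1 symbol for each of 16098 probe sets (30.0%), 0 probe sets had several symbols, and 37519 were unnamed here. All 16098 Entrez identifiers were found in the RefSeq gene table of assembly GRCh38.p14, which was used for gene biotypes and to look for older symbols in the lists, of which 0 needed updating. No coordinates are given, since no build is named for the deposited table. Where a gene had several probe sets, the one with the highest mean of both arrays stood for it. A gene counted as measured when that mean was at or above the median over all probe sets (3.70), which left 10258 of 14884 named genes.

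Differences are log2 values of the cMyc shRNA array minus those of the control shRNA array. With 1 array per group there is no spread between replicates, so no test was run and no p-value is given. A fixed rule of size, at least 2-fold, was used to count genes. The only repeat measurement is between probe sets: over the 416 genes with 2 or more measured probe sets, the SD of 1 probe set's log2 difference was 0.34, taken from how far the 2 highest probe sets of a gene lay apart. It is technical, and it does not hold the variation between cultures or between infections. Some of these probe sets are copies that can share probes, and over the 337 genes whose probe sets lay at least 0.1 apart in level the SD was 0.37.

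A total of 49 gene lists were fixed before the data were examined, as were the measured-gene rule, the 2-fold rule and the choice of named genes. Of their 1157 distinct genes, 662 were named on the array and 618 measured. For each list with at least 5 measured members, the median log2 difference was set against the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was counted as standing apart when its median lay in the lowest or highest 2.5% of the random medians. This describes these 2 arrays, since genes are not replicates. By definition 1.15 of the 46 lists that could be placed would lie on each side with unrelated genes. The rule for named genes took MYC and the measured MYC-MAX network, the 10 genes highest and the 10 lowest by log2 difference apart from those with a locus, microRNA or open-reading-frame type of symbol, up to 2 members farthest in the direction of each discussed list with the 1 farthest the other way, and the range of the housekeeping list. Other genes are named as chosen after their values were seen.

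The calculations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. They were tested on simulated data for this comparison, with 10258 genes at the levels and local spread of the real ones. This spread was taken from the observed differences between the 2 arrays, so it includes any real ones. The 2-fold rule picked 49 of 50 genes changed 4-fold, 43 of 50 changed 3-fold, 29 of 50 changed 2-fold and 11 of 50 changed 1.5-fold, and also 244 of 10058 unchanged genes. Of 200 random lists of 20 unchanged genes, 6 stood apart, and of 50 lists shifted by 0.5 on the log2 scale, 49 did. A set of 11 alternatives was fixed with the lists: 3 other scalings, 2 level filters, another rule for probe sets, 2 other rules of size, all probe sets, unmatched random lists and means in place of medians. Another 3 were added after seeing the data: members that belong to 1 list only, random lists drawn outside the interferon and cell cycle lists, and the probe sets lying apart in level.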

Results

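Messenger RNA levels were compared between HT1080 fibrosarcoma cells that had received an shRNA against cMyc and cells that had received a non-targeting shRNA, both harvested 48 hours after infection. MYC encodes a transcription factor that drives growth and proliferation genes. There was 1 array for each condition, with 53617 probe sets on each, and 10258 named genes were measured. The array medians were 3.68 for the control and 3.73 for the cMyc shRNA on the log2 scale, and the log2 values of the 2 arrays correlated across all probe sets, which are not independent replicates, with r = 0.973. No difference below has a replicate check, and each describes these 2 arrays. Single log2 differences carry a technical SD of 0.34, estimated between probe sets of 1 gene.

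MYC itself, the target of the shRNA, read 7.09 on the control array and 6.16 on the cMyc shRNA array (probe set 17072669), a log2 difference of -0.93, or 1.91-fold lower. It was the lowest difference in its network of 10 measured members, none of which reached 2-fold. MXD3 had a difference of -0.74 and MXI1 of -0.33, while MXD1, like them a MAX partner that opposes MYC, had +0.66. MAX, the common dimerisation partner, differed by 0.09, and the remaining members MLX (-0.20), MXD4 (-0.11), MNT (-0.07), MGA (-0.01) and MLXIP (0.08) lay closer to 0 than 0.34. MYC was read by 1 probe set, and among the 500 genes nearest to it in level 43 had a lower difference, so its direction matched its label without standing out in size.

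Across the 10258 measured genes, 206 were at least 2-fold higher on the cMyc shRNA array and 410 at least 2-fold lower, and 9642 lay within 2-fold. At least 4-fold, 47 genes were higher and 49 lower. Of the 10 highest genes, 9 belonged to the interferon-stimulated list and the other was EGR1, an immediate early transcription factor. Of the 10 lowest, 7 belonged to the list of G2/M and mitotic genes. A total of 4 gene lists stood above and 15 below the central 95% of matched random lists, and 27 lay inside. In simulated data with the same levels and spread, 244 of 10058 unchanged genes passed the 2-fold rule. That spread includes any real differences, so 244 may overstate the noise. Without replicates, individual genes near 2-fold still cannot be separated from noise.

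**Figure D1:**
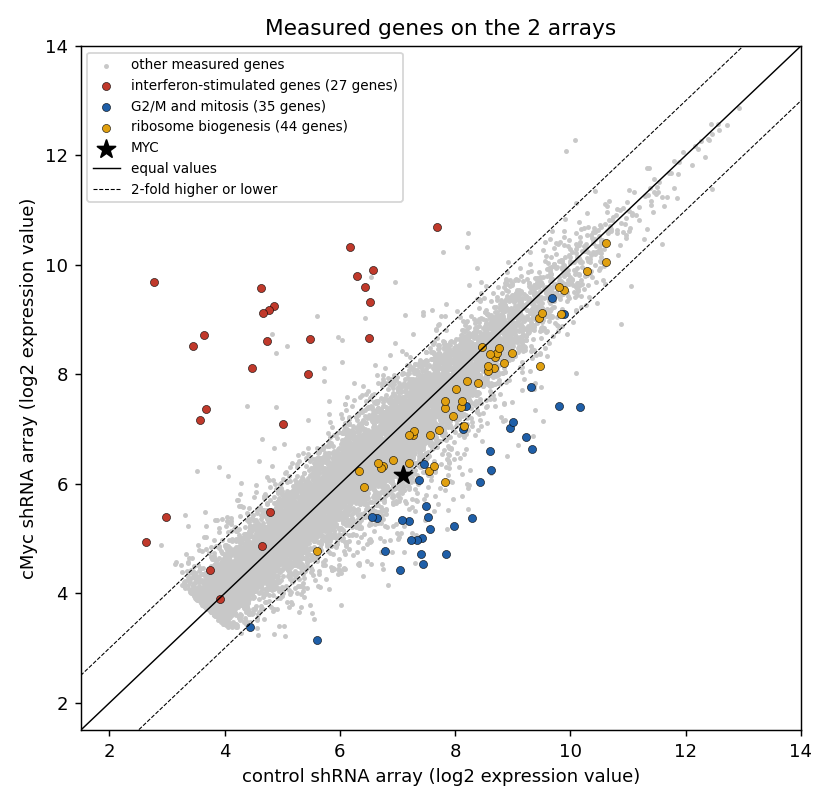
Each point is 1 of 10258 measured genes, with its log2 expression value on the control shRNA array (x axis) and on the cMyc shRNA array (y axis); solid and dashed lines mark equal values and a 2-fold difference. Of the interferon-stimulated genes (red) 23 of 27 lie above the upper dashed line, 32 of 35 G2/M and mitotic genes (blue) lie below the lower one, and MYC (star) lies just inside it at -0.93.

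Interferon-stimulated genes, which cells switch on in antiviral defence, were far higher on the cMyc shRNA array. The list had 27 measured members with a median log2 difference of 3.35, or 10.2-fold higher, with quartiles of 2.36 and 4.28. At least 2-fold higher were 23 members and at least 2-fold lower was 0. IFIT1, which binds foreign RNA, read 2.78 on the control array and 9.68 on the cMyc shRNA array, a difference of 6.90 (120-fold). IFIT2 was 34.1-fold, RSAD2 31.1-fold, IFIT3 21.8-fold, IFI44 21.3-fold, USP18 21.0-fold, SAMD9 17.9-fold and DDX60 14.6-fold higher. IRF7 was the member farthest the other way, at -0.02. The list median lay above all 10000 random medians, the central 95% of which ran from -0.23 to 0.17. The control values of IFIT1 (2.78), IFIT2 (3.63) and IFIH1 (3.45) were below the median of all probe sets (3.70). So were those of IFI44L (2.63), BST2 (2.98), MX2 (3.57) and HERC5 (3.68). No detection call is available there, so the sizes of those folds are uncertain. With no level filter the list median was 3.17.

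Receptors and effectors that sense viral nucleic acids were also higher. Of the 11 measured members of the sensing list, 5 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.73 (1.66-fold). IFIH1, a cytosolic sensor of long double-stranded RNA, was 33.6-fold higher and TLR3, the endosomal one, read 4.89 and 8.40 (11.4-fold higher). The others past 2-fold, named here after their values were seen, were AIM2 (3.03), RIGI (3.01) and EIF2AK2 (2.12 on the log2 scale). MAVS, the adaptor of the cytosolic RNA sensors, differed by -0.28. IFIH1 and RIGI also stand in the interferon list, and without shared members, or with no level filter, the sensing median was 0.23 and inside the random range. Class I antigen presentation had 5 measured members of 16 and a median of 0.56, with B2M, the class I light chain, at 1.01 on its brighter probe set and 0.53 on the other, and ERAP2 at 0.79, while CALR was nearest to 0 at 0.01. Its median was reached by 80 of 10000 random lists. The cytokine list had a median of 0.09, inside the random range, although PTGS2, the inducible cyclooxygenase, was 5.32-fold higher and the chemokine CCL2 4.04-fold lower.

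Genes of mitosis formed the lowest of the 46 lists. All 35 measured members of the G2/M list were lower on the cMyc shRNA array, 32 of them at least 2-fold, with a median of -2.13 (4.38-fold lower) and quartiles of -2.43 and -1.41. KIF20A, a kinesin of cytokinesis, went from 7.84 to 4.72 (8.67-fold lower), and the kinases PBK and TTK were 7.58-fold and 7.52-fold lower. PLK1 (6.73-fold), FOXM1, the transcription factor of the G2/M programme (6.70-fold), the proliferation marker MKI67 (6.50-fold) and the spindle checkpoint gene MAD2L1 (6.47-fold) followed. The 3 other genes among the 10 lowest were outside the list: DEPDC1 (6.67-fold), SKA3, a kinetochore component, and CDCA8, a subunit of the chromosomal passenger complex (both with a log2 difference of -2.68). DEPDC1 differed by -2.74 on its brighter probe set and by -1.04 on the other. BUB3 was the member nearest to 0, at -0.29. The list median lay below all 10000 random medians.

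DNA replication and G1/S genes were lower as well. Of 27 measured members 18 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.26 (2.39-fold lower), below all 10000 random medians. DTL was 5.52-fold and the cyclin CCNA2 5.18-fold lower, whereas the replication clamp PCNA differed by 0.01. The separate list of G1 cyclins, kinases and inhibitors had 9 measured members and a median of -0.38, inside the random range of -0.41 to 0.32. No inhibitor was measured: CDKN2A was below the level filter and the others had no named probe set. The list median lay below the random range under 3 alternatives, among them the level filter at the 75th percentile (-0.47). In it RBL1 (-1.26) and CDK2 (-1.08) were past 2-fold lower and CDK6 (1.17) past 2-fold higher. Together the G1/S and G2/M lists held 50 of the 410 genes at least 2-fold lower.

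**Figure D2:**
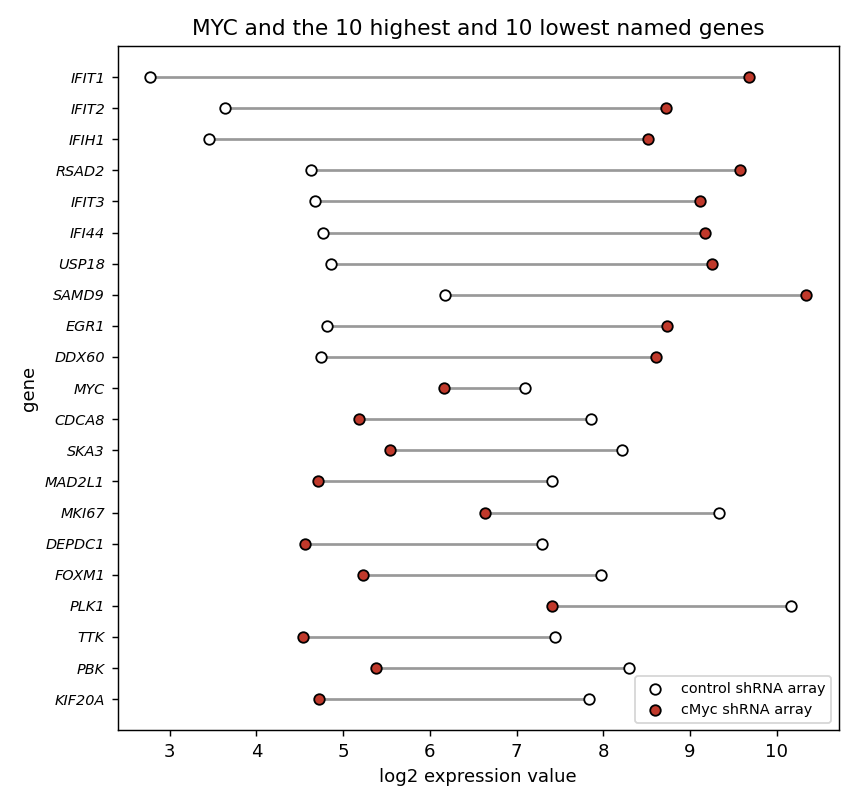
Log2 expression value (x axis) of MYC and of the 10 highest and 10 lowest named genes (y axis) on the control shRNA array (open circles) and the cMyc shRNA array (red circles), joined by a line per gene. IFIT1 spans 2.78 to 9.68, KIF20A spans 7.84 to 4.72, and MYC has the shortest line, 7.09 to 6.16.

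Nucleotide and one-carbon metabolism genes were lower on the cMyc shRNA array. All 18 measured genes of purine and pyrimidine synthesis were below 0, 10 of them at least 2-fold, with a median of -1.11 (2.16-fold lower). RRM2, a subunit of ribonucleotide reductase, was 4.75-fold and thymidylate synthase TYMS 3.12-fold lower, and CTPS2 was nearest to 0 at -0.05. The serine, glycine and one-carbon list had 3 of 10 members at least 2-fold lower and a median of -0.79. PSAT1, an enzyme of serine synthesis, was 4.24-fold lower, TYMS, which both lists hold, came next, and CTH lay farthest the other way at 0.28. Both medians lay below all 10000 random medians.

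Ribosome biogenesis genes, a class of MYC targets, were lower by a smaller amount. Of 44 measured members 43 were below 0, with a median of -0.43 (1.35-fold lower) and quartiles of -0.68 and -0.32, below all 10000 random medians. At least 2-fold lower were 5 members, led by LYAR (3.48-fold) and RRP1B (-1.32 on the log2 scale), and LTV1 differed by 0.04. The list of MYC-bound metabolic and proliferation genes had all 17 measured members below 0 and 4 at least 2-fold lower, with a median of -0.49, which 3 of 10000 random medians reached. FASN, fatty acid synthase, was 3.21-fold and SRM, spermidine synthase, 2.32-fold lower, and CCND2 was nearest to 0 at -0.23. With members that belong to other lists left out, its median was -0.40 and inside the random range. The list of genes described as repressed by MYC had 10 measured members of 30 and a median of -0.17, inside the random range of -0.31 to 0.27, with THBS1 at -1.06 and TIMP2 at 0.38. CDKN1A, CDKN1B, CDKN2B, GADD45A and the list's collagens and integrins had no named probe set here, so its median does not cover them.

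Further growth lists were also lower on the cMyc shRNA array. Small nucleolar RNA host genes had a median of -0.68, with SNHG16 (2.39-fold) and SNHG15 (2.21-fold) lowest and ZFAS1 nearest to 0 at -0.18. Fatty acid synthesis had -0.65, with FASN and FADS1 (2.26-fold) lowest and ACSS2 at 0.11. Nuclear transport had -0.62, with RANBP1 (2.04-fold) and CSE1L (1.92-fold) lowest and NUP160 at 0.19. Glycolysis had -0.59 with all 9 measured members below 0, from LDHA (2.24-fold) and HK2 (1.95-fold) to GAPDH (-0.19). RNA splicing factors had -0.47, with U2AF2 (2.00-fold) and HNRNPU (1.92-fold) lowest and HNRNPC at 0.16. Cholesterol synthesis (-0.44; MVD -1.10, SQLE -0.60, INSIG1 0.35), polyamine and glutamine metabolism (-0.43; SRM -1.21, ODC1 -0.81, GLUL 0.45), mitochondrial translation (-0.26; MRPL45 -1.49, MRPS27 -0.99, MRPS22 0.55) and ribosomal proteins (-0.25; RPL30 -1.15, RPL29 -0.86, RPL8 0.01), whose probes can also read near-identical pseudogenes, stood apart too. The calls of these last 4 lists ended under at least 1 alternative each, and the polyamine median was 0.10 without members shared with other lists.

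Lysosome and autophagy genes were slightly higher. Of 20 measured members 17 were above 0, none reached 2-fold in either direction, and the median was 0.33 (1.26-fold higher), which 6 of 10000 random medians reached. HEXA, a lysosomal hexosaminidase subunit, was highest at 0.66 and NEU1 next at 0.56, and the transcription factor TFE3 lay farthest the other way at -0.60.

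**Figure D3:**
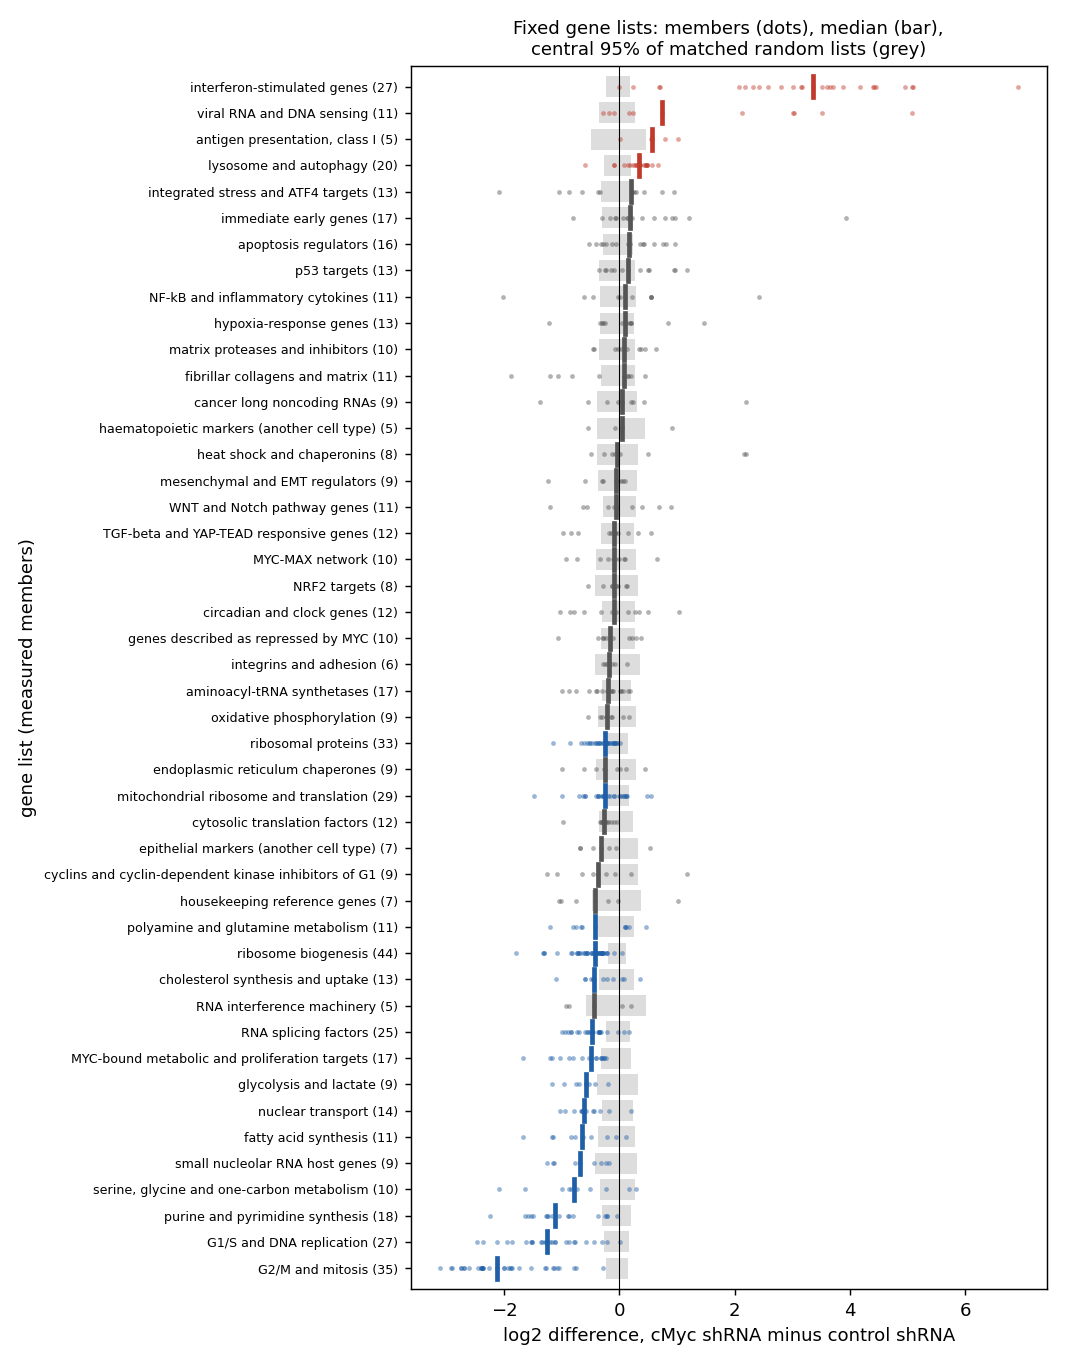
Log2 difference (x axis, cMyc shRNA minus control shRNA) for the 46 gene lists with at least 5 measured members (y axis, number measured in brackets): dots are genes, bars are list medians and grey bands are the central 95% of 10000 matched random medians. The 4 lists in red lie above and the 15 in blue below their bands, from 3.35 for interferon-stimulated genes to -2.13 for G2/M and mitosis.

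Other lists lay inside the random range as deposited. Their medians were 0.20 for integrated stress and ATF4 targets, 0.18 for immediate early genes, 0.17 for apoptosis regulators, 0.15 for p53 targets, 0.09 for hypoxia, 0.08 for matrix proteases, 0.07 for matrix genes, 0.05 for cancer long noncoding RNAs, -0.04 for heat shock, -0.05 for mesenchymal regulators, -0.06 for WNT and Notch, -0.09 for each of the TGF-beta and YAP, NRF2 and clock lists, -0.18 for adhesion, -0.20 for aminoacyl-tRNA synthetases, -0.22 for oxidative phosphorylation, -0.25 for endoplasmic reticulum chaperones, -0.26 for cytosolic translation factors and -0.45 for the RNA interference machinery. These medians cover only the measured part of each list. The matrix list had 11 measured members of 31 and no collagen, and adhesion had 6 of 24 and no integrin. Oxidative phosphorylation had 9 of 39, with no NDUF, SDH or ATP5 gene. The p53 list had 13 of 25, without CDKN1A, MDM2 or FAS. With means in place of medians, immediate early genes (0.48) and heat shock genes (0.49) lay above the random range and matrix genes (-0.38) below it. With the level filter at the 75th percentile the clock list (-0.62) lay below it, and ATF4 targets had -0.35, still inside. EGR1 read 3.93 higher on its brighter probe set and 1.34 higher on the other. SPRY4, a feedback inhibitor of growth factor signalling, was 1.20 higher. Within the matrix list THBS2 was 3.69-fold lower, while FBN1 was 0.44 higher. HSPA1A (2.20) and HSPA1B (2.15, chosen after its value was seen) were the highest heat shock genes, and since they are near-identical copies their signals cannot be separated. The 7 measured housekeeping genes had a median of -0.43, inside the random range, and ranged from -1.04 for HPRT1 to 1.01 for the brighter B2M probe set. That median was nearly as low as the one of ribosome biogenesis, and the random range for 7 genes was wide, from -0.48 to 0.37.

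Haematopoietic markers of another cell type had a median of 0.04 over 5 measured genes, inside the random range, with CD68, a lysosomal protein of macrophages that already read 10.4 on the control array, at 0.91. Epithelial markers had a median of -0.31 over 7 genes, inside the random range, with KRT18 at -0.69 and CLDN7 at 0.53, and lay below the random range (-0.35) after quantile normalization. Only 4 endothelial and muscle markers were measured, too few to be placed among random lists, with a median of 0.76. DES, an intermediate filament of muscle, was 2.35-fold higher on its brighter probe set, with a difference of -0.38 on the other, TTN, a giant protein of the sarcomere, was 1.87-fold higher, and MYOG lay farthest the other way at -0.05. Histone and proteasome lists had 0 named members here, and 12 of the 41 interferon-stimulated genes, such as MX1 and OAS1, were not analysed here because no named probe set stood for them.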

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

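The counts here were chosen after the counts over named genes were seen, and stand here because these probe sets carry no gene name and enter none of the counts of named genes or gene lists. Of the 15819 probe sets at or above the level filter that carry no gene name here, 577 were at least 2-fold higher on the cMyc shRNA array than on the control array, up to a log2 difference of 5.03. In the other direction 748 were at least 2-fold lower, down to -4.33. Their genes are not analysed here.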

How the results depend on the processing

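The alternatives were set before the data were examined, except that the use of members of 1 list only, of random lists outside the interferon and cell cycle lists, and of probe sets apart in level was chosen after seeing the data. Centring, quantile normalization and loess left MYC between -0.94 and -0.87 and the counts between 203 and 228 higher and between 367 and 417 lower, sharing at least 198 higher and 365 lower genes with the main counts. The size rule moved the counts by construction: 900 higher and 1224 lower at 1.5-fold, and 113 higher and 196 lower beyond 3 local robust SDs. Taking every probe set, unnamed ones included, gave 803 and 1177, and the level filter at the 75th percentile, which tests fewer genes, gave 126 higher. With members of 1 list only, 2 lists in place of 4 stood above random lists, since the sensing list (0.23) lay inside the range and the class I antigen list was left with under 5 members and not placed. The MYC-bound list then had -0.40 and was inside the range, and the polyamine list turned to 0.10; these lists are smaller by construction, and the cause was not tested further. Of the 19 lists that stood apart, 13 did so under all alternatives that gave them a value, among them the interferon, G2/M, G1/S and ribosome biogenesis lists. The other 6 were the MYC-bound, sensing, polyamine, cholesterol, ribosomal protein and mitochondrial translation lists. Another 6 lists that lay inside the range as deposited stood apart under at least 1 alternative: G1 cyclins (-0.47 at the 75th percentile filter, and -0.38 with the mean over probe sets or unmatched random lists), clock genes (-0.62 at that filter), epithelial markers (-0.35 after quantile normalization), and, with means of members, heat shock genes (0.49), immediate early genes (0.48) and matrix genes (-0.38). Of 173 values of named genes under other scalings, filters and probe set rules, 171 moved by less than 0.34. Averaging probe sets moved EGR1 to 2.63 and DEPDC1 to -1.89. Many of these values were fixed by construction, so the count says little about robustness. A level filter does not change the value of a gene it keeps, and centring shifts all genes alike. Averaging changes only genes with several probe sets. No paired analysis was possible because each condition has 1 array and the labels carry no replicate numbers. Leaving out an array leaves no comparison, and signal over background is unknown, so differences of dim genes are the least certain.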

Other observations

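The tests on mitotic genes were chosen only after their list median was seen, while those on interferon-stimulated genes were set after the highest genes had been seen but before the tested values were. Gene families outside the fixed lists were chosen after their values were seen, so their medians are given as values only. Among 15 measured protein-coding genes with CENP symbols outside the lists, which name centromere proteins, 9 were at least 2-fold lower and the median was -1.20, with CENPU (-1.78) and CENPV (-1.77) lowest. Among 34 kinesins outside the lists 10 were at least 2-fold lower, led by KIF14 (-2.26) and KIF18B (-2.14), while KIF16B was higher by 1.34 and the family median was -0.19. Mitochondrial import genes had a median of -0.43 over 22 members, with TOMM34 (-1.55) and TIMM21 (-1.47) lowest. Exosome subunits had -0.41 over 10 members, with EXOSC2 at -1.91. Of 43 TRIM genes 5 were at least 2-fold higher, TRIM38 by 2.45, with a family median of 0.06. The 345 measured microRNA genes had a median of 0.09. Under the 3 other scalings each of these family medians had the same sign. Zinc finger genes with ZNF symbols, also looked at, had a median of 0.01 over 360 members, which changed sign with loess (-0.00075).

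Single genes noticed after their values were seen included further antiviral genes outside the lists. DDX60L was 10.8-fold, IFITM1 9.48-fold, SP110 6.63-fold, PLSCR1 6.57-fold and SAMHD1 6.02-fold higher on the cMyc shRNA array. TRANK1 was higher by 3.46 on its brightest probe set. The chemokine CCL5 was 4.56-fold higher, against the 4.04-fold lower CCL2. The long noncoding RNA MIR31HG was 4.56-fold higher and DANCR 2.59-fold lower. TBL1XR1, a corepressor subunit, was 5.25-fold lower, and EIF4EBP1, a repressor of cap-dependent translation, 4.09-fold lower.

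Interferon-stimulated genes had a median of 3.35 on the cMyc shRNA array relative to the control. A scale or intensity trend left in the deposited values is argued against for a median of this size. The lowest median under 3 other scalings was 3.34, and loess moved genes by a median of 0.03. The columns were already on nearly the same scale, so these scalings could hardly move the median. They do not test other differences between the arrays. Haematopoietic cells as the whole cause are argued against. The 8 named markers had a median of 0.043, under the bound of 0.5 set beforehand, and LYZ and TYROBP, abundant in myeloid cells, differed by 0.05 each. Of the 8 markers 3 were below the level filter, LYZ among them. The argument therefore holds only as far as such dim probe sets can read these cells. CD68, at 0.91 from a reading of 10.4, would hide a small share. The control cells were infected with a hairpin virus too, so a response to any such virus would be on both arrays at equal dose. The doses were not compared here. What stays open is a response to this shRNA or its dose of vector, which may form double-stranded RNA, against the lower MYC level. With 1 active shRNA these cannot be told apart. The prediction that interferon genes would be higher got no value, since 0 of them were named on the array.

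Mitotic genes had a median of -2.13. A scale or intensity trend left in the deposited values is argued against here too, with a highest median of -2.10 under 3 other scalings. Again these scalings could hardly move the median, and they do not test other differences between the arrays. A smaller share of HT1080 cells, replaced by cells that lack adhesion, matrix protease and mesenchymal genes, is argued against. The 25 measured genes of these lists had a median of -0.055, with quartiles of -0.28 and 0.09. Some of them were dim on both arrays, and a share of other cells that express them is not tested. The matrix list, left out of this set, had a median of 0.07, with 3 of 11 measured members at least 2-fold lower. Loss of MYC, slower growth in an interferon-exposed state and another effect of this shRNA may each lower these genes and cannot be told apart here, because all 3 would fall on the same array. The G2/M median lay 1.70 below that of ribosome biogenesis (a difference of -1.70), which does not decide between them.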
